A study of Rattus norvegicus with 3 samples.

How the data were processed

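RNA labelled as rat adrenal medulla was measured on 1-colour short oligonucleotide arrays after 1 day (2 arrays) or 7 days (1 array) of cold. Groups and replicate letters were taken from the sample titles. The titles put the words Multiple Organs before the tissue, and these were read as a project name, which is a guess. The deposited table holds 1 linear intensity per probe set and array, which the authors had already summarised and scaled. The 2% trimmed mean was 2501 on each of the 3 arrays (2500.66, 2500.99 and 2501.03), so the arrays appear to have been scaled to a common trimmed mean. That reading rests on the values, and the software and its settings are not given in the sources used here. The median intensity was 1583, 593 and 675 on 1-day array a, 1-day array b and the 7-day array. Such scaling sets the total signal equal on every array, so it raises all values of an array with weak signal, spike-ins included, and a difference in total RNA between samples is not visible.

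All values were kept as scaled, since the trimmed means were within 5% of each other, and turned into log2(intensity + 16). The pseudocount of 16 shrinks differences of dim probe sets. The 57 control probe sets were left out of all gene comparisons and used to describe the arrays. Of the remaining 31042, the 15521 with a mean log2 value at or above the median of all (9.60, an intensity of 759) were kept. Gene names came from the platform annotation, with 20826 probe sets of 1 symbol, 436 of several and 9780 of none. Of those with 1 symbol, 20764 were updated to current symbols through their Entrez identifier in the RefSeq gene table of assembly GRCr8, used for names only. A gene was represented by the kept probe set with the highest mean, which gave 9292 genes. Levels of different probe sets were not compared.

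The planned test was limma's lmFit and eBayes with an intensity trend, two-sided with Benjamini-Hochberg adjustment at 0.05, on all 3 arrays. Its 1 residual degree of freedom comes from the 1-day pair, and the 7-day array was assumed to vary like the 1-day arrays. The prior degrees of freedom came out infinite, so limma gave all weight to the intensity trend of the spread. Each SE is thus the spread fitted at that intensity, not the spread of the probe set's own 1-day pair. A rule of size counted probe sets at least 2-fold beyond both 1-day arrays. For 30 gene lists on pathways and cell types, fixed before the data were examined, camera with a preset correlation of 0.01 was run on the 28 with at least 5 measured members. The fits were repeated with each 1-day array in the lone place. The 7-day array was also set against 1-day array b without a test, as planned for leaving out array a. That setting was given more room than planned after the quality of array a was seen. The position of a list median among 10000 random lists, drawn from genes of like mean intensity, served there as a description.

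Named genes followed a rule fixed before the data were examined. It took all genes passing limma, or, with fewer than 10, also the 12 highest and 12 lowest by the smaller of their differences from the 1-day arrays. It added 23 genes fixed in advance, of which 22 passed the filter, and the 4 members of each called list with the largest difference among those outside both 1-day arrays. Other list members named in the text were chosen after their values were seen. A rule added later took the 12 highest and 12 lowest against 1-day array b alone.

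Alternatives were pseudocounts of 1 and 64, quantile normalisation, centring on the median, no filter, a filter at the 75th percentile, limma without a trend and with robust = TRUE, the mean of all probe sets of a gene, camera with an estimated correlation, fry, random-list percentiles and leaving out each 1-day array. A filter on 1-day array b and the 7-day array, and removal of a loess trend on intensity (span 0.5), were added later. R 4.3.3 with limma 3.58.1 was used, and Python 3.11.15 with matplotlib 3.10.9 for figures. 

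The scripts' steps were tested on simulated arrays built on the real probe set means, in 10 runs of 15521 probe sets with 200 changed. With all 3 arrays given the spread between 1-day array b and the 7-day array, limma recovered 3.15%, 28.3%, 99.3% and 100% of probe sets changed 1.5-fold, 2-fold, 4-fold and 8-fold in the comparison of 7 days with 1 day. With 1-day array a given its own spread it recovered 0% of each, and the 2-fold rule against both arrays recovered 6.14%, 27.4%, 77.1% and 93.1%. Lists shifted by 0.4 log2 among 9359 genes were found by camera in 2 of 20 cases and by the random-list position in 18 of 20 in that second setting, while 7.87% of unshifted lists fell outside the random range. Noise was drawn independently for each probe set, so that share does not cover lists whose members vary together and may be too low for them.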

Results

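The series measured RNA levels in the adrenal medulla of rats held in the cold, with 1 oligonucleotide array per sample and 31099 probe sets per array. The adrenal medulla is the inner part of the adrenal gland, whose chromaffin cells make and release adrenaline and noradrenaline under stress. Of the 3 arrays, 2 came from 1 day of cold (replicates a and b) and 1 from 7 days. No array of rats kept out of the cold was analysed here, so the comparison open to these data is a longer against a shorter stay in the cold. The labels do not say whether replicates a and b came from separate animals, so the spread between them may be technical, and the number of arrays limits the precision of every value.

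The 7-day array and 1-day array b had nearly the same profile, and 1-day array a stood apart from both. Over the gene probe sets, the Spearman correlation across probe sets was 0.939 for 1-day array b with the 7-day array, 0.664 for the 1-day pair and 0.684 for 1-day array a with the 7-day array. Among the 15521 probe sets kept, the SD of the log2 difference was 1.43 between the 1-day arrays and 0.39 between 1-day array b and the 7-day array, and the counts at least 2-fold apart were 6950 and 373. Probe sets of one array are not independent replicates, so these correlations describe the arrays.

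Genes of the chromaffin cell itself, and of the adrenal cortex, were among those on which the 1-day arrays parted. Slc18a1, a transporter that loads catecholamines into secretory vesicles, read 1390 on array a and 18040 on array b, and Cyp11b1, an enzyme of corticosterone synthesis in the adrenal cortex, read 2012 and 33603. Chga, which encodes the granule protein chromogranin A, went the other way, with 628429 on array a and 157202 on array b. The median of 13 chromaffin cell markers was -0.69 (log2, array a minus array b), and that of 27 oxidative phosphorylation genes was -1.14.

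Control probe sets separated the arrays in the same manner. The ratio of the 3′ to the 5′ beta-actin probe set, which climbs when RNA is degraded or poorly copied, was 231 on 1-day array a, 6.11 on 1-day array b and 8.87 on the 7-day array, and the same ratio for GAPDH was 5.02, 1.79 and 1.87. The 18 hybridisation spike-in probe sets had a geometric mean of 187534, 16829 and 21788 on the 3 arrays in that order. Values against 1-day array b alone are given in their own comparison further on. Those 2 arrays also differed in their controls, with spike-ins 1.29 times as high on the 7-day array. RNA quality was not tested as a cause of differences between them.

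**Figure D1:**
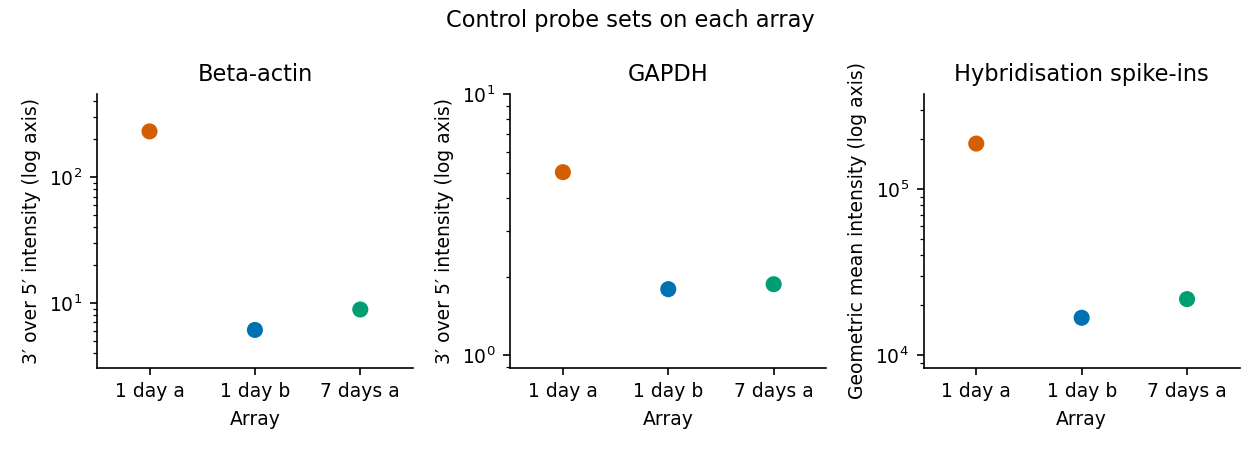
Each panel plots 1 measure of the control probe sets (vertical log axis) for the 3 arrays (horizontal axis), with 1 point per array. The 1-day array a lies above the others in all 3 panels, with a beta-actin ratio of 231 against 6.11 and 8.87.

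**Figure D2:**
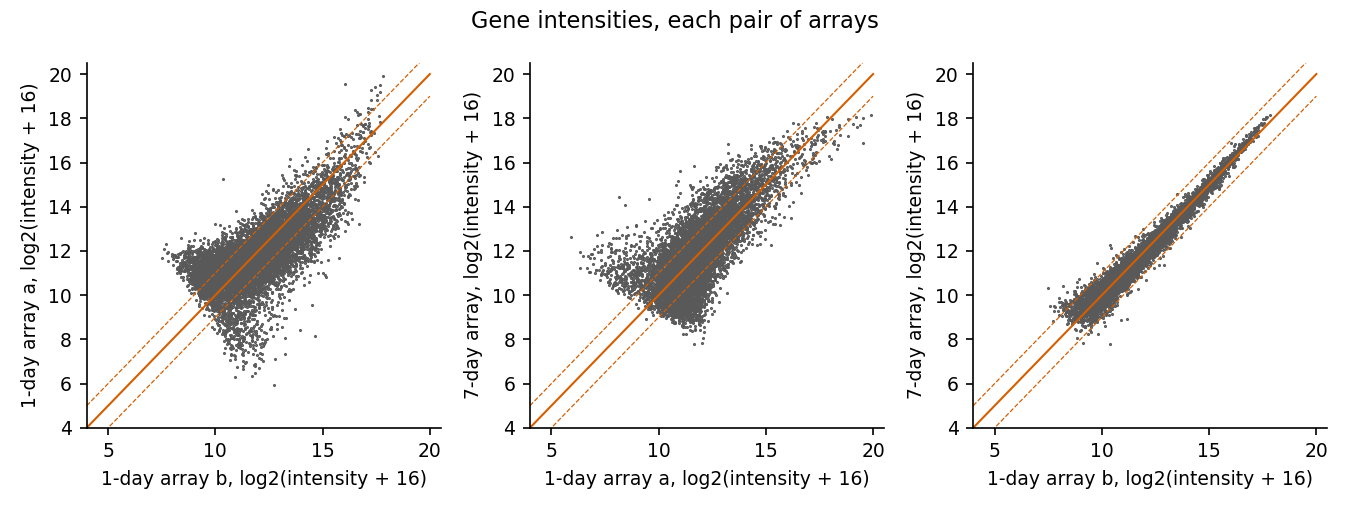
Each point is 1 of 9292 genes, with log2(intensity + 16) on 2 arrays on the axes, the solid line marking equal values and the dashed lines a 2-fold difference. Points scatter widely wherever 1-day array a is on an axis and lie close to the line for 1-day array b against the 7-day array.

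The comparison of 7 days with 1 day of cold, with both 1-day arrays used, asked which genes and gene groups differ between the lengths of exposure. Limma's camera was run on 28 gene lists. With 1 array at 7 days, it takes genes as its units and does not count the spread between 7-day samples. Its calls therefore describe that array and do not test the length of exposure. The lists of oxidative phosphorylation, fatty acid synthesis and oxidation, cholesterol synthesis and uptake, and proteasome subunits were called higher on the 7-day array. Interferon-responsive genes were called lower. In that order, the median log2 difference from the mean of the 1-day arrays was 0.63, 0.64, 0.58, 0.38 and -0.28, and against 1-day array b alone it was 0.19, 0.17, 0.16, 0.19 and -0.35. Of the 5 calls, 0 held with an estimated correlation between genes or with fry, and 0 were made with each array centred on its median. The estimated correlation and fry rest on the 1 residual degree of freedom, which leaves almost no room for a call. Their lack of calls is therefore no evidence against the lists. The proteasome call was lost with quantile normalisation (adjusted p = 0.497) and against random lists of like intensity (percentile 73.6), the interferon call without a filter (adjusted p = 0.0550), and these and the fatty acid call with the 75th percentile filter (adjusted p = 0.117 to 0.584). Adrenal cortex markers had a median of 0.42 (0.36 against array b, adjusted p = 0.0587) and were called only with quantile normalisation (adjusted p = 0.0258), without a filter (adjusted p = 0.0180) and with the mean of all probe sets (adjusted p = 0.00128). The lists of catecholamine synthesis, storage and breakdown (0.56, but -0.22 against array b, adjusted p = 0.112) and of chromaffin cells (-0.11, and -0.16 against array b, adjusted p = 0.779) were not called.

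In the oxidative phosphorylation list 24 of 27 measured members read above both 1-day arrays and 0 read below both. Its 4 named members, Ndufa4, Uqcrfs1, Uqcrc2 and Sdha, all subunits of the respiratory chain, lay 2.46 to 3.10 above 1-day array a on the log2 scale, and 0.05 to 0.29 above 1-day array b, though Ndufa4 (0.05) turned to -0.06 with quantile normalisation, -0.03 with the intensity trend removed and -0.13 with median centring, where Uqcrfs1 (0.15) also turned, to -0.03. The fatty acid list had 13 of 18 members above both, with Cpt2, of mitochondrial fatty acid import, at 299 on 1-day array a, 5259 on 1-day array b and 6781 on the 7-day array, and with Srebf1, Acadm and Me1 at 0.14, 0.15 and 0.46 above array b. The cholesterol list had 12 of 19 above both, with Sqle (0.20 above array b), Idi1 (0.58), Ebp (0.05) and Dhcr7 (0.26), all enzymes of cholesterol synthesis. Of 24 proteasome subunits, 18 read above both, among them Psma5 (0.19 above array b), Psma1 (0.26), Psmb7 (0.06) and Psmb3 (0.17).

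Interferon-responsive genes had 9 of 19 members below both 1-day arrays and 4 above both. The antiviral GTPase genes Mx1 and Mx2 read 430 and 1121 at 7 days against 1090 and 2534 on 1-day array b, and 2766 and 2610 on 1-day array a. Rsad2, an antiviral enzyme gene, and Irf7, a transcription factor of the interferon response, were lower than 1-day array b by log2 differences of -0.75 and -0.60 and lower than 1-day array a by -1.68 and -1.89. Of the genes of antigen presentation on the list, B2m stood at 0.20 (-0.01 with quantile normalisation), Psmb8 at 0.16 (-0.02 with median centring) and Tap1 at -0.09 relative to 1-day array b. Over all 9292 genes, 24.8% read above both 1-day arrays at 7 days and 24.9% below both.

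No single probe set passed in limma: 0 of 15521 had an adjusted p under 0.05, 70 had an unadjusted p under 0.05, and the lowest adjusted p was 1.00. Adjusted over the list alone, 0 members passed in each of the 30 lists, the lowest adjusted p in limma being 0.121, for an adrenal cortex marker. With 1-day array a in the place of the lone array, limma called 9684 probe sets, and camera called oxidative phosphorylation, fatty acid and catecholamine genes lower on that array. With 1-day array b in that place, limma called 0 and camera 5 lists, catecholamine genes again among them but higher on that lone array.

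By size, 6 probe sets lay at least 2-fold above both 1-day arrays and 53 at least 2-fold below both. With 1-day array b in the lone place the same rule gave 13 higher and 274 lower. With 1-day array a there it gave 3122 higher and 2796 lower. The 7-day array thus stood apart by this rule in the fewest probe sets, so the counts do not point to the length of exposure. The highest gene was Gsta4, a glutathione transferase that clears products of lipid peroxidation, at 4458 on the 7-day array against 1523 and 1369 at 1 day (1.62 ± 0.97 on the log2 scale, SE from limma). The SEs given here come from limma's intensity trend and do not measure how well a gene's own 1-day values agreed. Among the next 7 genes were Serpinc1, which encodes antithrombin (1.15 ± 0.92), Creg1 (1.02 ± 0.98), Pzp (1.11 ± 2.51) and Rpa2 (0.96 ± 1.83), which stood 1.08, 1.06, 0.94 and 0.86 above 1-day array b alone. Also among them, Smim30l1 (3.35 ± 2.34), Anapc16 (2.41 ± 0.94) and Hmg20b (1.95 ± 1.41) rested largely on 1-day array a, where they read 64, 440 and 354, and stood 1.06, 0.86 and 0.82 above 1-day array b. Uqcc5, Csrnp3, Serpina11 and B4galt7 lay 0.76 to 0.81 above 1-day array b.

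The lowest genes against both 1-day arrays were Numbl, a gene of neuronal differentiation (202 on the 7-day array, 3194 and 1309 at 1 day), Bex2 (447, against 2770 and 1855) and Slc31a2, a copper transporter gene (287, against 2226 and 874). Sobp, the adenylyl cyclase gene Adcy5, Mx1, the calcium channel gene Trpv6, Zfp329, Mx2, Ttc39a, Vwa3a and Itgb2, an integrin of white blood cells, followed, at -1.55 to -1.13 relative to 1-day array b. Numbl, Slc31a2, Trpv6 and Vwa3a were kept only because of their level on 1-day array a, and did not pass a filter on the other arrays. In simulated arrays in which 1-day array a kept its own spread, 56.5 unchanged probe sets per run met the size rule, against 59 observed here. The simulated spread was set from these same arrays, any effect of exposure included, and was alike for all probe sets of an array. The closeness of the counts is therefore no test of whether the observed probe sets changed.

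Set against 1-day array b alone, the 7-day array read lower for neuropeptide, catecholamine, matrix and interferon genes and higher for adrenal cortex, proteasome, oxidative phosphorylation, cholesterol and fatty acid genes. This compares those 2 arrays, not the conditions, so it carries no p-value, and each list median is placed among the medians of 10000 random lists of the same size and intensity. Of 28 lists, 13 lay below the central 95% of random lists, 5 above and 10 inside. Against 1-day array a, 9 of these 13 had a median above 0 and 4 below, and 5 of the 5 one above. Among single genes 286 probe sets were at least 2-fold higher and 87 at least 2-fold lower on the 7-day array. That split became 167 and 202 with each array centred on its median and 156 and 78 with quantile normalisation. It was 177 and 142 with the intensity trend removed, a trend strongest among dim probe sets (median 0.29 in the dimmest 10% kept). Centring moved the median of all kept probe sets from 0.00 to -0.18, so list positions below are relative to other genes, and members between 0 and 0.18 turn negative on that scale.

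Catecholamine genes were mostly lower on the 7-day array, with 10 of 13 lower, a median of -0.22 and a place at percentile 0.020 of the random lists. Th, the rate-limiting enzyme of catecholamine synthesis, read 193597 on 1-day array b and 224786 on the 7-day array, Dbh 188289 and 215877, and Pnmt, which makes adrenaline, 147037 and 176819, differences of 0.22, 0.20 and 0.27 that became -0.14, -0.12 and 0 with quantile normalisation and 0.01, -0.01 and 0.08 with the intensity trend removed. Gch1, which makes the cofactor of tyrosine hydroxylase, read lower (61950 and 43515, -0.51), as did Ddc (-0.23, with 0.14 on a second probe set), Maoa (-0.24) and the vesicular transporter genes Slc18a2 (-0.48) and Slc18a1 (-0.40). On 1-day array a the order differed, and the median of 7 days against that array was 1.41.

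Neuropeptide and secretory granule genes had a median of -0.24, below all random lists, with 16 of 21 members lower, while against 1-day array a it was 0.56 with 15 of 21 higher and with both 1-day arrays 0.12. The neuropeptide precursors Calca (5382 and 3063, -0.81), Penk, of the enkephalins (45064 and 29224, -0.62), Tac1 (-0.54), Nts (-0.52) and Vgf (-0.47) were the lowest. Npy stood at -0.04 (-0.45 with quantile normalisation and -0.21 with the intensity trend removed) and Gal at -0.20. The granins Chga (0.35) and Chgb (0.31) read higher, but stood at 0.06 and 0 with quantile normalisation and at 0.16 and 0.08 with the intensity trend removed. Of 15 exocytosis genes 10 were lower (median -0.24, percentile 0.425), with Cadps at -0.44, Rab3c at -0.41 and Snap25 at -0.29. Of 14 ion channel and acetylcholine receptor genes 10 were lower (median -0.20, percentile 1.92), including the nicotinic subunit Chrnb4 (-0.55) and the sodium channel Scn3a (-0.70). Of 12 peptide and hormone receptor genes 9 were lower (median -0.20, percentile 2.14), with Agtr1a at -0.48, Agtr2 at -0.30 and Adcyap1r1 at -0.43. The channel and receptor lists moved inside the random range with quantile normalisation, with no filter, with the mean of all probe sets and with the intensity trend removed, and the channel list also with the 75th percentile filter.

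Chromaffin cell markers, 6 of 13 of which are also on the lists above, had a median of -0.16 (percentile 0.030), with 7 lower and 6 higher, and 0.26 against 1-day array a. Among the lower, the transcription factor Gata3 read 16594 on 1-day array b and 9008 on the 7-day array (-0.88), and Phox2a stood at -0.47 and Stmn2 at -0.51. Among the higher were Hand2 (0.26), Chga and Chgb.

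**Figure D3:**
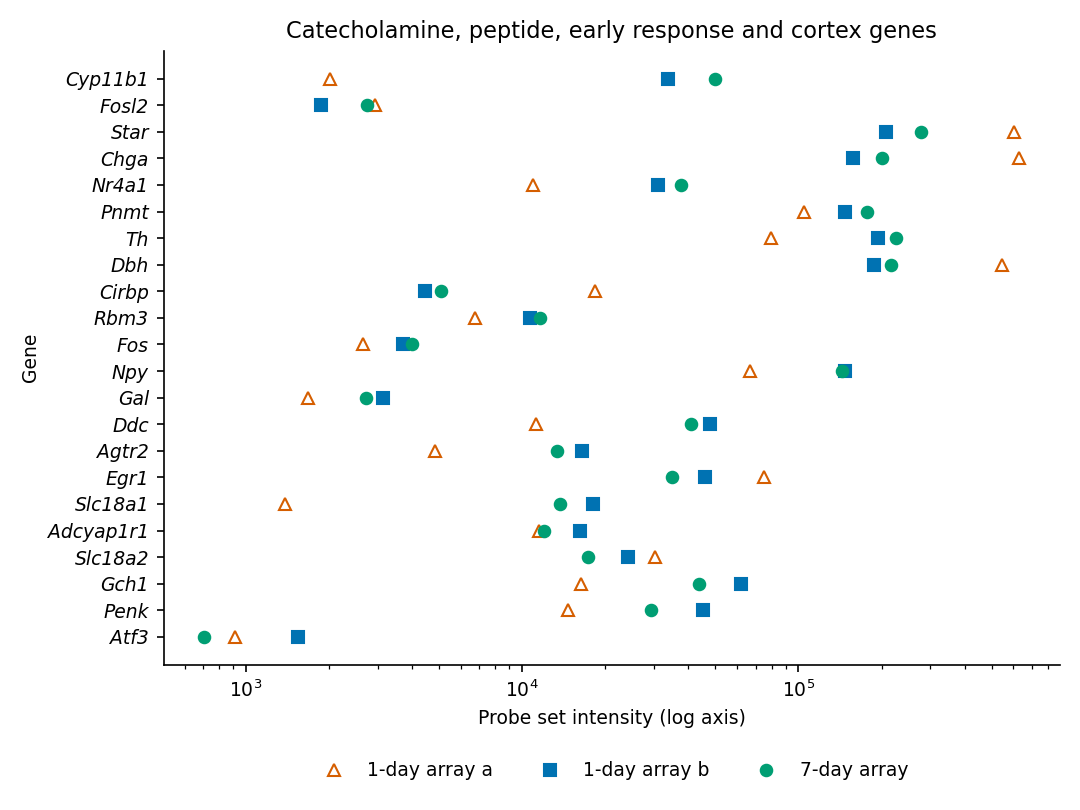
Probe set intensity (horizontal log axis) of 22 genes fixed in advance (vertical axis), with 1 symbol per array and genes ordered by the 7-day array minus 1-day array b. Values of 1-day array b and the 7-day array lie near each other, from Atf3 (-1.11) to Cyp11b1 (0.57), while 1-day array a departs in either direction.

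Early response genes, which nerve stimulation induces within minutes, had a median of -0.14 (percentile 0.26), with 19 of 29 lower, and 0.02 against 1-day array a. Atf3 (1541 and 707, -1.11), Zfp36 (-0.86), Ier2 (-0.62), Fosb (-0.56), Dusp1 (-0.43) and Egr1 (-0.40) were lower, and Fosl2 (0.56), Nr4a1 (0.28) and Fos (0.11) were not. Heat shock genes had a median of -0.10 (percentile 0.805), which moved inside the random range with the intensity trend removed (-0.06) and was 0.65 against 1-day array a. Among them Cryab stood at -0.61, Hspb8 at -0.58, Bag3 at -0.46 and Hspa1a at -0.33, and the mitochondrial chaperones Hspd1 and Hspe1 at 0.35 and 0.31, which became 0.03 and 0.11 with quantile normalisation and 0.15 and 0.13 with the intensity trend removed.

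Interferon-responsive genes had a median of -0.35 relative to 1-day array b, below all random lists, with 14 of 19 lower, and against 1-day array a it was -0.44 with 10 lower and 9 higher. Beside Mx1 (-1.31), Mx2 (-1.17), Rsad2 and Irf7 these included Ifit2 (-0.66), Gbp2 (-0.56), Ifit3 (-0.54) and Isg15 (-0.44). Inflammatory genes had a median of -0.29 (percentile 0.2) with 11 of 12 lower, led by the adhesion molecule gene Icam1 (4250 and 1626, -1.38) and the chemokine Ccl2 (-0.69), while against 1-day array a their median was 0.27 with 7 of 12 higher. Markers of macrophages and lymphocytes also read lower (median -0.19, percentile 0.92, 13 of 16 lower), but higher against 1-day array a (0.36, 13 of 16 higher). Relative to array b, Fcer1g stood at -0.63, Tyrobp at -0.62 and Cd163 at -0.63, and Ptprc, a marker of white blood cells, was opposed at 1.15.

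Extracellular matrix genes had a median of -0.35, below all random lists, with 15 of 20 lower, while against 1-day array a it was 0.19 with 10 of 20 higher and with both 1-day arrays 0.08. Collagen genes Col6a1 (-0.66), Col4a1 (22561 and 14394, -0.65), Col1a1 (-0.47), Col4a2 (-0.45) and Col3a1 (-0.42) and Sparc (-0.36) were lower, while Lox, which cross-links collagen (0.65), Mmp2 (0.58) and Nid1 (0.43) were higher. Fibroblast and pericyte markers, which share collagen genes with that list, had a median of -0.17 (percentile 1.33), but 0.44 against 1-day array a, with Dpt at -0.74 and Pdgfra at -0.48.

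Adrenal cortex markers had the highest median of the 28 lists, 0.36 (percentile 99.99), with 14 of 15 higher. Star, which carries cholesterol into mitochondria, read 208111 and 277066 (0.41), Cyp11b1 33603 and 49727 (0.57), Scarb1, which takes up cholesterol from lipoproteins, 107334 and 151029 (0.49), Hsd3b1 164869 and 214950 (0.38) and Cyp21a1 142187 and 182108 (0.36). Dlk1 was the exception at -0.47. Star, Cyp11b1, Scarb1, Hsd3b1 and Cyp21a1 stood at 0.18, 0.55, 0.38, 0.10 and 0.17 with quantile normalisation. With the intensity trend removed these 5 stood at 0.19, 0.51, 0.33, 0.18 and 0.17. The dimmest 10% of kept probe sets read higher on the 7-day array, with a median of 0.29. Bright probe sets as a group also read higher there, with a median of 0.05 in the brightest 10% of kept probe sets. That group spans mean log2 values from 13.92 to 17.98, so its median understates the trend for the brightest markers. Removing the trend lowered Star, with a mean log2 of 17.87, from 0.41 to 0.19. The random range for this list, matched on intensity, ran from 0.02 to 0.25. With the intensity trend removed the median of the markers was 0.18 (percentile 99.94).

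Cholesterol genes had a median of 0.16 (percentile 99.39), and 13 of 19 read higher, with Insig1 at 0.61, Idi1 at 0.58, Acat2 at 0.57 and Cyp51 at 0.55. Fatty acid genes had a median of 0.17 (percentile 99.4), with Fads2 at 0.61 and Me1 at 0.46. With each array centred on its median these medians became -0.02 and -0.01, and their place above the random lists stayed. Proteasome subunits had a median of 0.19, above all random lists, with 22 of 24 higher, and oxidative phosphorylation genes 0.19 (percentile 99.15), with 26 of 27 higher. Ribosomal protein genes also had a median of 0.18 and 20 of 20 higher, but the median turned to -0.03 with quantile normalisation, and probe sets as bright lay there too (percentile 33.1).

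Beside ribosomal proteins, the lists inside the random range were those of cyclic AMP and mitogen signalling (median 0.02), glucocorticoid-responsive genes (-0.12), the unfolded protein response (-0.05), cold-inducible and thermogenic genes (0.12), glycolysis (0.03), cell division (-0.15), the circadian clock (0.05), Schwann and sustentacular cells (0.09) and endothelial cells (0.04). The cold-inducible RNA-binding protein genes Rbm3 and Cirbp stood at 0.12 and 0.19, and Cry2 of the clock list at 0.76. Erythroid and adipocyte markers had 2 and 4 measured members, with medians of 0.09 and -0.05, and were not tested. Glucocorticoid-responsive genes lay below the random range with a pseudocount of 1, quantile normalisation, the 75th percentile filter and the intensity trend removed (percentiles 1.24 to 2.45), and clock genes lay above it with no filter and with the mean of all probe sets (97.7 and 98.6).

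Of 468 list members, 50 changed sign between these 2 arrays with quantile normalisation, 110 with median centring, which shifts every gene alike, and 36 with the intensity trend removed. Of the 63 that differed by 0.5 or more, 0 did with quantile normalisation or the trend removed. A second probe set of the same gene often differed, with the opposite sign for Uqcrc2 (-0.18), Col1a1 (0.08), Lox (-0.03) and Zfp329 (0.10). Across 2131 genes with at least 2 probe sets kept, the differences of the pair had a Pearson r of 0.245 and a Spearman rho of 0.251, genes not being independent replicates, and of 165 genes differing by 0.5 or more on the brighter probe set, 68.5% had the same sign on the other.

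**Figure D4:**
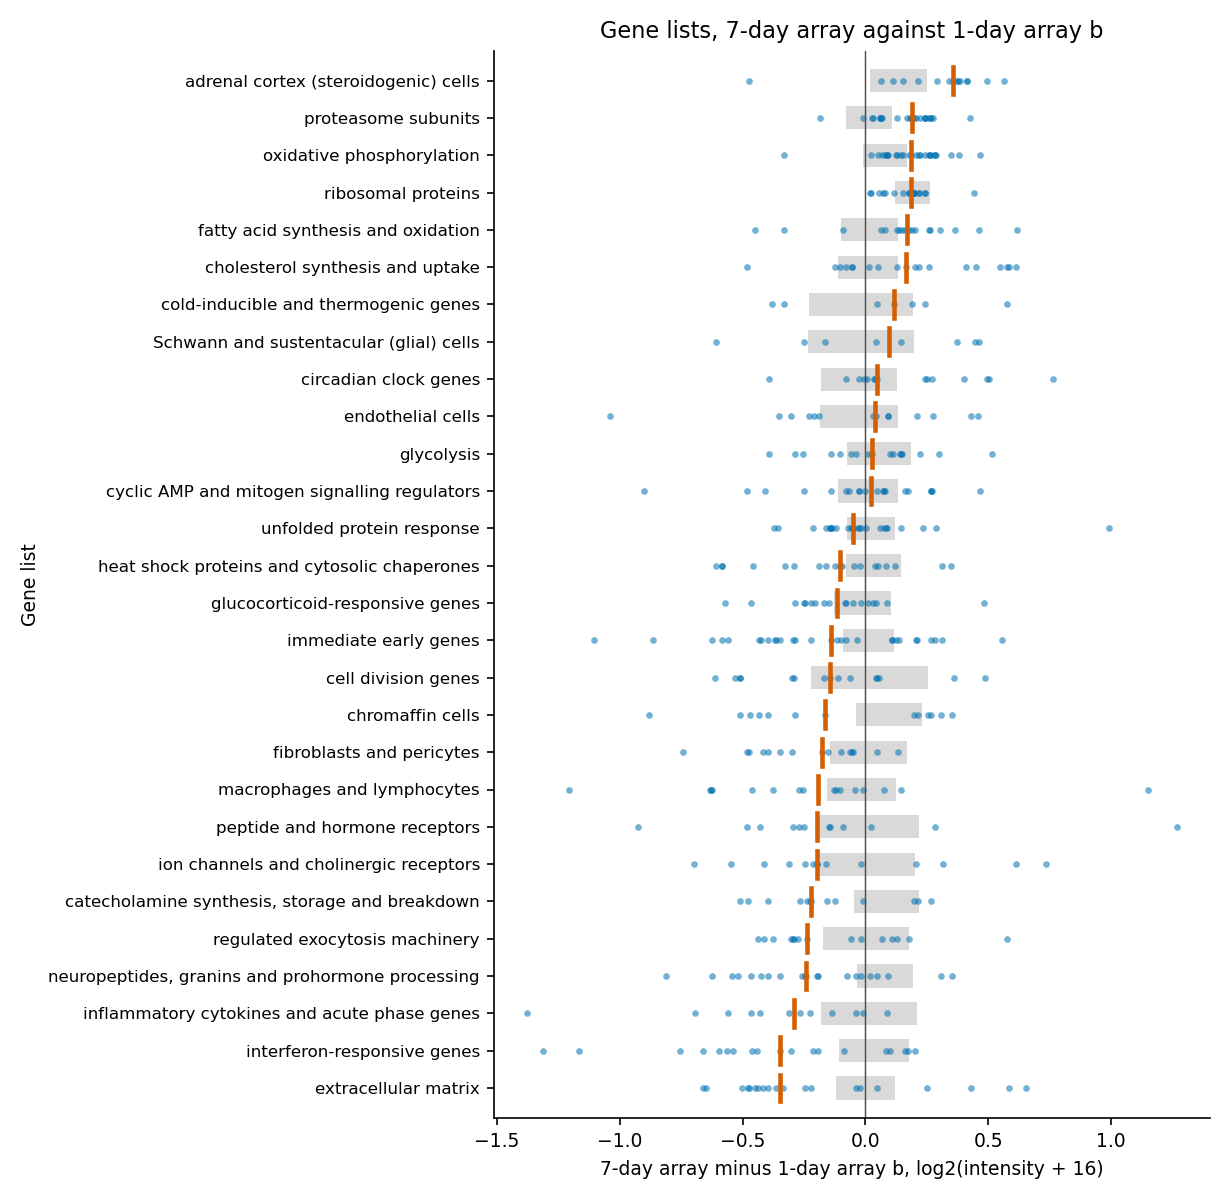
The 28 tested gene lists (vertical axis) with the log2 difference of each member, 7-day array minus 1-day array b (points, horizontal axis), the list median (upright bars) and the central 95% of medians of 10000 matched random lists (grey). Adrenal cortex markers (median 0.36) lie highest, and extracellular matrix and interferon-responsive genes (-0.35 each) lowest.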

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

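The comparison of splits was planned, but what it should show was written after its counts were seen, and the tests of RNA quality, other tissue, scaling, immune cells and cortex tissue were chosen only after the results they bear on were seen. Control probe sets, which no gene comparison used, set 1-day array a apart. Its ratio of 3′ to 5′ beta-actin was 231, and its spike-ins read 11.1 times those of 1-day array b. No explanation of this pattern by length of exposure was tested, since array b shares the label.

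Poor or scarce labelled RNA may account for the distance of 1-day array a. Its beta-actin ratio was 26.0 times the higher of the other arrays and its spike-ins 8.61 times, and scaling an array of weak signal to a common mean raises its spike-ins. Another tissue on that array would need chromaffin markers far lower than on array b, and their median was -0.69 (bootstrap SE 0.61), which argues against it. A mixed sample stays open. The words Multiple Organs, whose meaning is not given, stand in the title of every array and so do not single out 1-day array a.

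The limma comparison gave 0 probe sets, and with 1-day array a in the lone place it gave 9684, the highest of the other splits. Since the real split gave 0, all 3 of the 3 possible splits had to give as many, so this count tests nothing, and 3 splits would be too few for a share under 0.05 in any case. A split that calls so many more points to a structure of the samples, but as its spread comes only from 1-day array b and the 7-day array, it restates the distance of 1-day array a and is no further evidence of it.

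Interferon-responsive genes read lower on the 7-day array than on 1-day array b (median -0.35). Scaling that depends on intensity was argued against as the whole cause, since random lists of like intensity did not read as low. With the intensity trend removed the median was -0.43, outside the central 95% of random lists (-0.13 to 0.13). As the median lay below all such matched lists before the removal, this is no independent test. Fewer immune cells on the 7-day array might account for the lower interferon genes. The macrophage and lymphocyte markers, 0 of 16 of which are on another list, lay above the interferon genes by 0.15 (bootstrap SE 0.18). That SE measures the spread among genes and not between samples. With 1 array on each side, this explanation cannot be told apart. Against 1-day array a the macrophage and lymphocyte markers read higher (0.36). Relative to array b, 13 of 16 were lower, with RT1-Ba at -1.21 and the abundant Cd74 and Lyz2 at -0.12 and -0.10. Ptprc was opposed at 1.15. A difference in the length of exposure, or between single animals or dissections, stays open and untested.

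Adrenal cortex markers read higher on the 7-day array (median 0.36). Removing the intensity trend lowered the median to 0.18, which argues against intensity as the whole cause, since the central 95% of random lists ended at 0.13. Those lists were matched on intensity and the median lay at percentile 99.99 before the removal, so this is no independent test. More cortex tissue in the 7-day sample is a candidate explanation, as 0 of 15 cortex markers are on another list and the abundant Star and Fdx1 stood at 0.41 each, or 0.19 and 0.20 with the trend removed. Cortex minus chromaffin markers, 15 and 13 genes, gave 0.29 (bootstrap SE 0.17) with the trend removed, within 2 SEs of 0. It cannot be told apart from no shift. That SE measures the spread among genes, so with 1 array on each side it could not separate tissue content from other causes. A change within cortex cells between 1 and 7 days of cold stays open and untested.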

How the results depend on the processing

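The filter on 1-day array b and the 7-day array, the removal of the intensity trend, and all settings for 1-day array b against the 7-day array were chosen after seeing the data. No paired analysis was possible because the groups share only the replicate letter a. Leaving out a 1-day array gives no test, so limma, camera and the agreement of the 1-day arrays have no value there, and the lone 7-day array cannot be left out. Signal over background was not measured, so how far it limits the counts is open. For the values below that moved, the cause was not tested.

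The limma count was 0 in every setting run, with 1 to 74 probe sets at an unadjusted p under 0.05. The number of lists called by camera was 5 or 6 except with each array centred on its median (0), the 75th percentile filter (2), an estimated correlation (0) and fry (0), but the lists differed. With 1 residual degree of freedom, an estimated correlation and fry left almost no room for a call. Quantile normalisation lost proteasome subunits (adjusted p = 0.497), no filter lost interferon genes (0.0550), and both, like the mean of all probe sets, gained adrenal cortex markers (0.0258, 0.0180 and 0.00128). Placed among random lists, proteasome subunits lay inside (73.6), and catecholamine (98.2) and exocytosis genes (2.19) outside. Centring turned the interferon median to 0.23 while moving the median of all kept probe sets to 0.48, so the interferon list stayed below other genes.

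Without a filter, 2171 probe sets were at least 2-fold from both 1-day arrays (389 higher, 1782 lower), 19258 lay that far apart between the 1-day arrays, and 6672 between the 7-day array and 1-day array b (4612 higher, 2060 lower). The 75th percentile filter gave 7 (2 higher, 5 lower), 2721 and 47 (33 higher, 14 lower). The number higher than both was 3 with quantile normalisation, 10 with median centring and 18 with the filter on 1-day array b and the 7-day array. Between these 2 arrays the count was 234 with quantile normalisation (156 higher) and 240 with that filter (154 higher), and the split was 167 higher and 202 lower with median centring and 177 and 142 with the intensity trend removed. Leaving out a 1-day array gave 373 (array a) to 6643 (array b) probe sets 2-fold from the other, with 286 to 3065 higher and 87 to 3578 lower.

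Of 362 list medians under other settings 33 changed sign, and of 250 for the 7-day array minus 1-day array b 12 did, of which 8 with median centring. The lists outside the random range numbered 16 to 19. Of 606 and 542 values of named genes, 19 and 15 changed sign.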

Other observations

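The genes in this part were all chosen after their values were seen, those of the first paragraph by rank among genes passing the filter on 1-day array b and the 7-day array. Genes such as Numbl (-2.60), Slc31a2 (-1.55) and Trpv6 (-1.26), which did not pass it, are left out of these ranks. The lowest on the 7-day array relative to 1-day array b were Krt19, a keratin of simple epithelia, at 2297 on 1-day array b and 463 on the 7-day array (-2.27), then Bex2 (-2.01), Cobl (-1.77), Sobp (-1.55), the muscle protein gene Mybpc1 (7578 and 2635, -1.52), C2cd4b (-1.40), Icam1 (-1.38), the potassium channel gene Kcnn3 (-1.37), Adcy5 (-1.32), Gpnmb (-1.31), Mx1 (-1.31) and Zfp329 (-1.24). The highest were Harbi1 (2.23), Spetex2l1 (1.88), Wnt1 (1.78), Cnga1 (1.76), Spata24 (1.76), Klhl21 (1.73), Gsta4 (1.69), Mrm3 (1.56), Mtarc1 (1.47), Kcnh3 (1.47), Rnf40 (1.35) and Dennd6b (1.35). With quantile normalisation Harbi1, Wnt1, Cnga1, Spata24 and Mrm3 stood between 1.18 and 1.72, and 1 of the 24 genes did not pass the filter. Most of the highest were dim on 1-day array b, with Harbi1 at 279 and Wnt1 at 481, and a second probe set gave 0.25 for Harbi1, 0.53 for Spata24, 0.43 for Mrm3 and 0.10 for Zfp329. Krt19 read 674 on 1-day array a, and Mybpc1 2511, nearer the 7-day array than 1-day array b in both cases. The same held for Cobl (345), C2cd4b (354), Icam1 (1298), Kcnn3 (201) and Gpnmb (1571). Bex2, Sobp, Adcy5, Mx1 and Zfp329 read higher on array a than on array b. Of the highest, Harbi1, Spetex2l1 (38631), Wnt1, Spata24, Mrm3, Mtarc1, Kcnh3 (4117) and Dennd6b read higher on array a than on the 7-day array. Cnga1, Klhl21, Gsta4 and Rnf40 read lower on array a than on the 7-day array.

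Other single genes departed from the lists they were placed on. The receptor gene Ret read 299 on 1-day array b and 742 on the 7-day array (1.27), among hormone receptors that were mostly lower, but was kept only because of its 2147 on 1-day array a and did not pass a filter on the other arrays. The endothelial gene Eng read 6664 and 3237 (-1.04) while its list had a median of 0.04, and Chac1 of the unfolded protein response read 794 and 1594 (0.99) against a list median of -0.05. Nr3c2, the mineralocorticoid receptor gene, stood at -0.93, Spry2 at -0.90 and Pgam1 of glycolysis at 0.51.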
